A study of Mus musculus with 18 samples.

How the data were processed

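Alveolar macrophages were taken from the lungs of mice by bronchoalveolar lavage and enriched on magnetic columns with CD11c beads, per the labels' protocols. The mice had conditional alleles of Vhl and Hif1a, of Vhl and Hif2a (gene symbol Epas1), or of all 3 genes, and each of the 3 knockouts had its own control group. The labels name CD11c-Cre, a recombinase expressed in CD11c-positive cells, for the knockouts, and for the controls they name the conditional alleles without saying whether Cre was absent. Each of the 6 groups held 3 libraries, 18 libraries in all, made from polyA RNA with a directional kit. A companion series on mice that lack Vhl alone is named in the series description and was not analysed here.

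The deposited table was taken to hold expected counts, that is, estimated numbers of reads per gene that need not be whole, for 32789 genes. The unit was taken from the values, since the labels do not name it: 89.251% of the values were whole numbers and the columns had different totals. Per the submitters' processing notes the reads were checked with FastQC, trimmed with cutadapt and aligned to GRCm38 with STAR; the versions, the counting tool, the annotation release and the strand setting are not given in the sources used here. How reads shared by overlapping genes were assigned is therefore unknown. No column of the table belonged to other samples.

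The deposited expected counts were rounded to whole counts, a step added once the values were seen to have decimals, and genes were filtered with filterByExpr of edgeR on the 6 groups with its default settings. This left 12900 genes tested and 19889 not tested, and the tested genes held 99.967% of all counts. Library sizes were scaled with TMM factors. Normalised counts (CPM) were computed with the scaled library sizes. Means are given with SD over the 3 libraries of a group. A quasi-likelihood model of edgeR with 1 coefficient per group was fitted to all 18 libraries, so that all groups shared 1 estimate of the spread, with no covariates. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate. Intervals and errors cover the spread between libraries and counting error, not the PCR step, since reads carry no molecular identifiers in the sources used here. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

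The comparisons were each knockout against its own control, the 3 differences between these effects (a test of the interaction contrast), the 3 control groups against each other, and the correlation across genes of the fold changes of the 3 knockouts, which share no library. Targeted genes were also compared with a two-sided exact permutation test of 3 libraries against 3, whose smallest possible p is 0.1. The tested genes were matched by identifier to GENCODE M21 on GRCm38 for positions, with 12882 of 12900 (99.86%) found; 49 symbols had more than 1 identifier, and a list then took the identifier with the highest mean CPM.

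Gene lists, 30 in all with 702 symbols, were fixed before the data were examined, as were the model, the tests, the rule for naming genes and all alternatives except those named last below. The lists covered glycolysis, other hypoxia-response genes, genes reported as HIF-2a-dependent, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, lipid and surfactant handling, alveolar macrophage identity, monocyte and interstitial macrophage markers, inflammatory cytokines and chemokines, the type I interferon response, MHC class II and antigen presentation, proliferation, oxidative stress and iron, alternative activation, lysosome and phagocytosis, the amino acid stress response, cytosolic ribosomal proteins, dissociation and immediate early genes, the sex of the animal and, for other cells, markers of neutrophils, dendritic cells, T and NK cells, B cells, eosinophils and mast cells, lung epithelium, endothelium and fibroblasts, and erythrocytes. Of the symbols, 5 were absent from the table (Atp5f1, Mx1, Mx2, Clec7a and Ear11). Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within each comparison; an estimated correlation and fry of limma were the alternatives. Genes were named by rule: Vhl, Hif1a and Epas1 in every comparison, and for each comparison the 10 highest and 10 lowest log2 fold changes among called genes with a mean CPM of at least 1, which for a knockout also had to separate every knockout library from every control library. Predicted models, clones, receptor segments and sex-linked genes were counted but not named. Members of the lists are given as examples.

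Total counts per library ran from 19230000 to 34015000 (rounded), so that 1 CPM was 19.23 to 34.015 counts before TMM scaling. On simulated counts with the real means, library sizes and spreads and 200 changed genes, the model recovered 43.75% of 1.5-fold and 72% of 2-fold changes in the Vhl/Hif1a comparison (12810 genes tested), 53.2% and 70% in the Vhl/Hif2a comparison (12781 genes) and 54.2% and 70% in the triple comparison (12806 genes). The share of false calls there was 4.03%, 3.27% and 5.70%. In the simulated differences of effects, 1.5-fold changes were recovered in 18.75% (Vhl/Hif2a minus triple), 16% (Vhl/Hif1a minus triple) and 14.9% (Vhl/Hif1a minus Vhl/Hif2a) of genes and 4-fold changes in 78%, 81.25% and 81.25%. False calls made up 4.20%, 8.46% and 5.65% of the calls in these differences, in the same order. The simulation used 1 mean per gene for all groups and held no library that stands apart. Recovery in the real comparisons may be lower, above all where few genes change, since the adjusted threshold is then stricter.

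The alternatives were median-of-ratios size factors, no filter on low counts, a stricter filter (CPM of at least 1 in at least 3 libraries), a replicate block, limma-voom with quality weights, DESeq2, a fit of only the libraries compared, direct comparison of knockout groups without their controls, a CPM minimum of 5 for correlations, and leaving out each library in turn. Alternatives chosen after seeing the data left out 2 control libraries with knockout-like transcripts or 3 libraries that stand apart, or added a minimum absolute log2 fold change of 1.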

Results

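RNA sequencing measured polyA transcripts in alveolar macrophages, the resident macrophages of the airspaces, from 3 crosses of mice. Vhl encodes the protein that marks the alpha subunits of the hypoxia-inducible factors for degradation, and Hif1a and Epas1 encode HIF-1α and HIF-2α. By the labels, 1 knockout lacks Vhl and Hif1a, 1 lacks Vhl and Hif2a (Epas1), and the triple knockout lacks all 3 genes. Each knockout had 3 libraries and its own control 3, which makes 18 libraries. The Vhl/Hif1a knockout libraries held 25851000 to 27050000 counts and their controls 22339000 to 25056000. The Vhl/Hif2a knockout libraries held 30787000 to 34015000 counts and their controls 19230000 to 25794000. The triple knockout libraries held 28090000 to 30962000 counts and their controls 24728000 to 30664000. All tests of genes are edgeR tests with n = 3 libraries per group and values ± SD for CPM and ± SE for log2 fold changes, unless stated otherwise.

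Vhl RNA fell in all 3 knockouts, in 3 of 3 libraries each. Vhl (ENSMUSG00000033933, chromosome 6, 113623959 to 113631633 on GRCm38) was at 2.88 ± 0.240 CPM against 16.9 ± 3.25 in the Vhl/Hif1a cross, 17.0% of control (log2 fold change -2.55 ± 0.16, edgeR adjusted p = 8.8e-08). It was at 2.25 ± 0.297 against 18.7 ± 1.30 CPM in the Vhl/Hif2a cross (12.04%, -3.05 ± 0.16, edgeR adjusted p = 7.6e-10) and at 2.20 ± 0.30 against 12.9 ± 1.20 CPM in the triple cross (17.0%, -2.56 ± 0.16, edgeR adjusted p = 1.2e-07). Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530) fell in the libraries labelled Vhl/Hif2a knockout, from 217 ± 33.3 to 66.3 ± 10.8 CPM, which is 30.5% of control (-1.71 ± 0.18, edgeR adjusted p = 4.3e-06). Its level did not pass the test in the Vhl/Hif1a knockout (193.5 ± 23.8 against 229 ± 3.29 CPM, edgeR adjusted p = 0.66) or in the triple knockout (239 ± 2.47 against 209 ± 62.4 CPM, edgeR adjusted p = 0.56). Epas1 (ENSMUSG00000024140, chromosome 17, 86753700 to 86833410) rose in the libraries labelled Vhl/Hif2a knockout, from 27.6 ± 6.47 to 54.2 ± 5.55 CPM (0.97 ± 0.19, edgeR adjusted p = 0.0019). Epas1 was at 47.9 ± 11.9 against 34.7 ± 1.39 CPM in the Vhl/Hif1a knockout (edgeR adjusted p = 0.26) and at 34.2 ± 3.93 against 40.4 ± 9.81 CPM in the triple knockout (edgeR adjusted p = 0.51). The two-sided exact permutation p was 0.1 for Vhl in each cross, the smallest that 3 libraries against 3 allow. It was also 0.1 for Hif1a and Epas1 in the Vhl/Hif1a and Vhl/Hif2a crosses, and 0.8 and 0.5 in the triple cross. Counts per gene also cover exons outside a deleted part, so the Hif1a and Epas1 counts do not check those deletions, and the knockouts are named here by their labels.

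**Figure D1:**
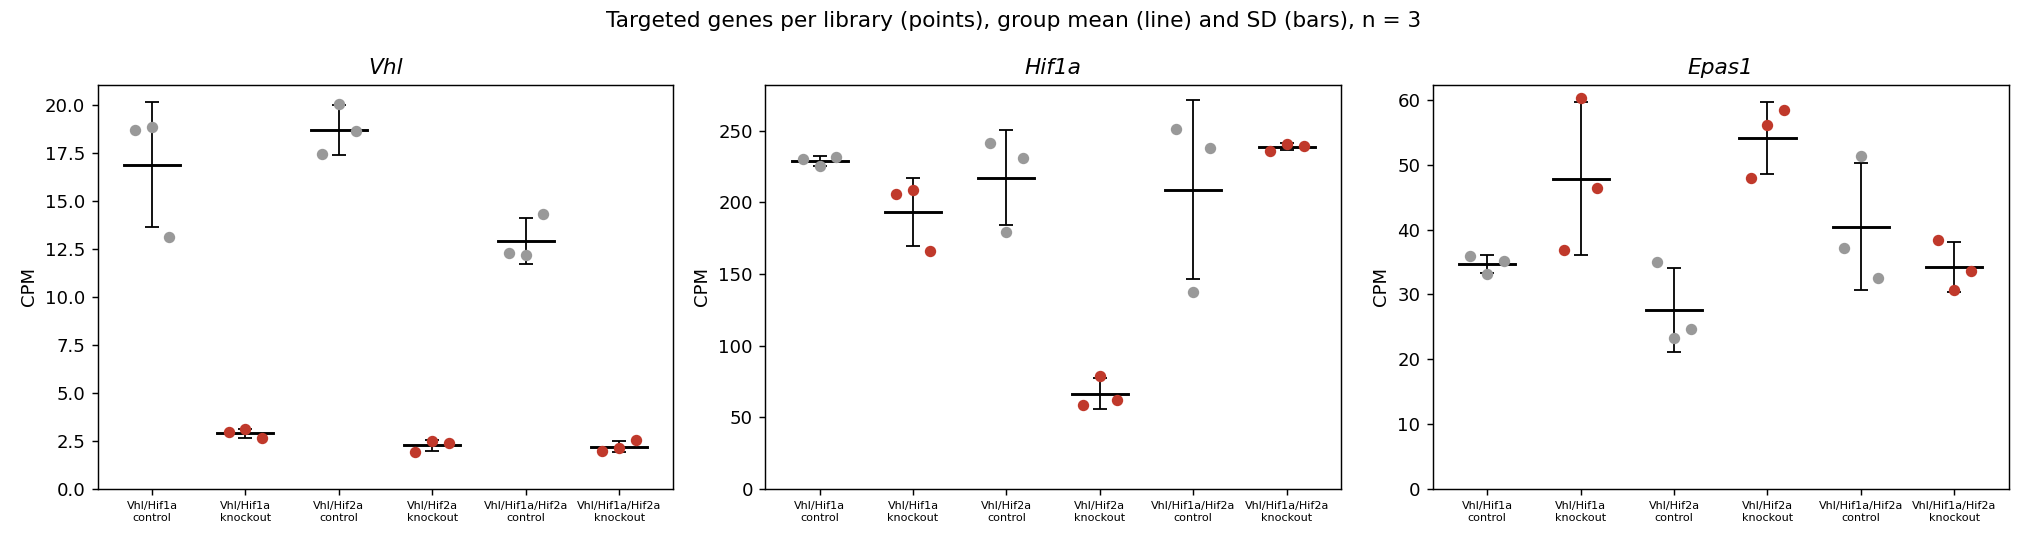
Vhl, Hif1a and Epas1 in CPM (linear axis from 0) in each library of the 6 groups, with points for libraries, a line for the mean and bars for the SD. Vhl lies between 2.20 and 2.88 CPM on average in the knockouts and between 12.9 and 18.7 CPM in the controls.

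With HIF-2α left, in the Vhl/Hif1a knockout, the genes with the largest increases included Egln3, a HIF prolyl hydroxylase that is itself a HIF target, at 485 ± 82.7 CPM against 11.2 ± 18.5 in control (5.41 ± 1.0, edgeR adjusted p = 0.0033). Arg1, the arginase of alternatively activated macrophages, rose from 1.47 ± 1.74 to 55.1 ± 25.2 CPM (5.19 ± 0.66, edgeR adjusted p = 8.3e-05), and F13a1, a coagulation factor subunit made by macrophages, rose from 0.246 ± 0.389 to 10.1 ± 4.27 CPM. C3ar1, the receptor for the complement fragment C3a, rose from 2.42 ± 1.68 to 45.1 ± 8.26 CPM, and Rtl5, a retrotransposon-derived gene, from 10.3 ± 5.64 to 170 ± 21.7 CPM. Sema3g (5.0 ± 0.66), Plcb4 (4.52 ± 0.31), Spsb4 (4.37 ± 0.49), Abcb4 (4.14 ± 0.46) and the hypoxia-response gene Ankrd37 (4.12 ± 0.40) also rose. Besides Vhl, the largest decreases included the chemokine Cxcl10 (-2.26 ± 0.36, edgeR adjusted p = 8.5e-04), Fam167a (-2.24 ± 0.29), Ece1, the endothelin-converting enzyme (1.81 ± 0.0589 against 6.89 ± 0.522 CPM), Adgre4 (-1.85 ± 0.37) and Spsb1 (-1.82 ± 0.25). Tnnt2 (-3.50), Ifit1bl1 (-2.33), Rsad2 (-1.78) and Il1b (-1.78) were also called lower, with calls that ended when single libraries were left out. Tnnt2 ended at -3.10 without knockout 2 (adjusted p = 0.068) and at -3.11 without control 2 (0.051), and it was -4.12 without knockout 3. Ifit1bl1 ended without knockout 2 (0.077), knockout 3 (0.078) or control 3 (0.099, at -1.58), and it was -3.30 without knockout 1. Rsad2 went from -1.78 to -0.82 without control 3 and ended as well without knockout 1 (0.097), 2 (0.14) or 3 (0.086). Il1b kept a log2 fold change of -1.95 to -1.47 where its call ended, without knockout 1 (0.13), 2 (0.094) or 3 (0.064), or control 1 (0.14) or 2 (0.085). Of 12900 genes tested, 469 differed at an adjusted p under 0.05, with 286 higher and 183 lower, and 1697 had an unadjusted p under 0.05. Without knockout 2, knockout 3 or control 2 the count was 299, 300 or 282. Control 3 held Egln3 at 32.5 CPM against 0.464 and 0.617 in the other controls, and without it the log2 fold change was 9.80 for Egln3, 6.79 for Arg1, 5.40 for Plcb4, 5.09 for Abcb4 and 4.96 each for C3ar1 and Spsb4, while F13a1 and Sema3g were left with 1 and 2 control counts.

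The gene group with the largest shift in the Vhl/Hif1a knockout was MHC class II and antigen presentation, whose products show peptides to CD4 T cells. Of its 14 tested members 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median log2 fold change of 1.76 (camera adjusted p = 3.9e-29 and adjusted p = 0.0017 with an estimated correlation). H2-Aa rose from 94.2 ± 53.6 to 1285 ± 110 CPM. Cd74, the invariant chain, rose from 386 ± 200 to 5014 ± 669 CPM, and Ciita, the transactivator of this gene family, from 8.50 ± 3.46 to 103 ± 17.5 CPM (3.59 ± 0.30, edgeR adjusted p = 7.5e-07). The member that fell was the costimulatory gene Cd80 (-0.54 ± 0.14). Of 11 tested dendritic cell markers, which share high class II levels, none passed (median -0.43, camera adjusted p = 0.012 and adjusted p = 0.50 with an estimated correlation), and neither of the 2 tested B cell markers passed (1 higher adjusted over the list alone, median 0.62, camera adjusted p = 0.63).

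Glycolysis genes were higher in part in the Vhl/Hif1a knockout: 8 of 23 rose and none fell (14 adjusted over the list alone). The median was 0.35 (camera adjusted p = 5.0e-14 and adjusted p = 0.065 with an estimated correlation). The glucose transporter Slc2a1 (1.72 ± 0.19), Tpi1 (1.09 ± 0.12), Pfkl (0.93 ± 0.14) and Ldha (0.35 ± 0.09) were among them, and the glycolytic kinase Pgk1 was at 130 ± 7.59 CPM against 140 ± 5.80 in control (edgeR adjusted p = 0.78). The glycolysis count was 4 without knockout 3 or without control 2. Of 41 other hypoxia-response genes 13 rose and 1 fell (17 and 1 adjusted over the list alone). The median was 0.41 (camera adjusted p = 2.9e-18 and adjusted p = 2.7e-04 with an estimated correlation). Bnip3, a mitophagy receptor (2.39 ± 0.17), Gpr35 (3.11 ± 0.27) and Ndrg1 (1.46 ± 0.21) rose, and Narf fell (-0.47 ± 0.12). Of 21 genes reported as HIF-2α-dependent, 2 rose and 4 fell (5 and 4 adjusted over the list alone). The median was -0.05, the mean 0.07 and the camera direction down (adjusted p = 0.93). Arg1 was among those that rose, and the iron exporter Slc40a1 (-1.13 ± 0.26), Spp1 (-0.59 ± 0.11), Csf1r (-0.37 ± 0.09) and Il1b fell.

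Some interferon, cytokine and division genes were lower in the Vhl/Hif1a knockout. Of 29 type I interferon response genes 6 fell (8 adjusted over the list alone), among them Ifit1 (-1.75 ± 0.32) and Gbp2 (-0.46 ± 0.12). The median was -0.37 (camera adjusted p = 2.4e-08 and adjusted p = 0.19 with an estimated correlation). The count was 1 without knockout 2, knockout 3 or control 3. Of 22 inflammatory cytokines and chemokines 6 fell (1 higher and 7 lower adjusted over the list alone), among them Tnf (-1.58 ± 0.37) and Il1a (-0.77 ± 0.17). The median was -0.51 (camera adjusted p = 7.5e-05 and adjusted p = 0.19 with an estimated correlation). The count was 2 without knockout 1, control 1 or control 2 and 3 without knockout 3. Of 32 proliferation genes 5 fell (21 adjusted over the list alone), among them Plk1 (-0.42 ± 0.10), a mitotic kinase. The median was -0.33 (camera adjusted p = 5.0e-14 and adjusted p = 0.0061 with an estimated correlation). The proliferation count was 0 without knockout 1 or control 2, 1 without knockout 2 or knockout 3, 2 without control 1 and 3 without control 3. Of 7 neutrophil markers, 1 rose (S100a8, 1.16 ± 0.19) and 3 fell, Csf3r (-1.37 ± 0.11), Cxcr2 (-1.45 ± 0.16) and Mmp8 (-0.80 ± 0.21). With 1 and 3 adjusted over the list alone, the median was -0.33 (camera adjusted p = 3.3e-04 and adjusted p = 0.029 with an estimated correlation).

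Genes of the macrophage itself moved in part in the Vhl/Hif1a knockout. Of 30 lipid and surfactant handling genes 4 rose (7 adjusted over the list alone), namely the lipid chaperone Fabp4 (1.10 ± 0.15), the nuclear receptor Nr1h3 (0.72 ± 0.10), Apoe (1.26 ± 0.21) and Apoc1 (1.26 ± 0.22). The median was 0.05 (camera adjusted p = 8.2e-04 and adjusted p = 0.19 with an estimated correlation). Of 34 alveolar macrophage identity genes 2 rose and 2 fell (5 and 3 adjusted over the list alone), with Fabp4 and Ctsk (0.52 ± 0.08) higher and Mertk (-0.40 ± 0.08) and Siglecf (-0.34 ± 0.09) lower (median 0.08, camera adjusted p = 0.17). Of 20 monocyte and interstitial macrophage genes 3 rose, F13a1, Itgam (1.34 ± 0.21) and Apoe (4 higher and 2 lower adjusted over the list alone). The median was -0.10, the mean 0.24 and the camera direction up (adjusted p = 0.41). Of 24 cholesterol synthesis and uptake genes 1 fell, Cyp51 (-0.50 ± 0.13; 1 adjusted over the list alone). The median was -0.21 (camera adjusted p = 3.3e-05 and adjusted p = 0.31 with an estimated correlation), and none of 49 cytosolic ribosomal protein genes passed (0 adjusted over the list alone). The median was 0.23 (camera adjusted p = 4.2e-08 and adjusted p = 0.53 with an estimated correlation).

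With HIF-1α left, in the Vhl/Hif2a knockout, the genes with the largest increases included 4 of the hypoxia-response list, Vegfa, Ak4, Egln3 and P4ha2. Vegfa, the vascular growth factor, rose from 1.03 ± 1.04 to 77.6 ± 14.8 CPM (6.27 ± 0.48, edgeR adjusted p = 8.8e-08), and Ndufa4l2, a mitochondrial protein induced in hypoxia, from 2.27 ± 2.65 to 149 ± 10.2 CPM (6.09 ± 0.49). Ak4, a mitochondrial adenylate kinase, rose from 1.81 ± 1.97 to 104 ± 10.2 CPM, Egln3 from 4.81 ± 5.88 to 316 ± 24.3 CPM (6.08 ± 1.06, edgeR adjusted p = 7.1e-04) and Mgarp from 0.438 ± 0.555 to 35.4 ± 1.42 CPM. Colgalt2 (6.43 ± 0.57), Hif3a (5.89 ± 0.63), Adm2 (5.88 ± 0.51) and Apbb1 (5.87 ± 0.54) also rose, and P4ha2, a collagen prolyl hydroxylase subunit, had 254 counts over the 3 knockout libraries and 2 over the 3 controls (2.64 ± 0.531 against 0.0299 ± 0.0266 CPM). Besides Vhl, the largest decreases included Fam167a (-3.37 ± 0.30, edgeR adjusted p = 4.8e-07), Unc5a (-3.31 ± 0.30), Igflr1 (-3.15 ± 0.35), the erythropoietin receptor Epor (-3.07 ± 0.43), Mfsd6 (-3.07 ± 0.17), Cyfip2 (-3.00 ± 0.46), Vash1 (-2.90 ± 0.27), Nat8l (-2.87 ± 0.31) and Syp (-2.81 ± 0.12). Of 12900 genes 1895 differed, with 991 higher and 904 lower, and 3397 had an unadjusted p under 0.05. Without knockout 1 the count was 1227. Control 1 had the highest control level of several of these genes, and without it the log2 fold changes were 7.27 for Vegfa, 7.52 for Ndufa4l2, 7.14 for Ak4, 7.69 for Egln3, 8.08 for Mgarp, 6.67 for Apbb1 and -2.22 for Cyfip2. Colgalt2 and Adm2 were left with 2 control counts each.

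Nearly the whole glycolytic pathway rose in the Vhl/Hif2a knockout: 18 of 23 genes were higher and 1 lower (20 and 1 adjusted over the list alone). The median was 1.98 (camera adjusted p = 4.4e-127 and adjusted p = 9.8e-06 with an estimated correlation). Pgk1 rose from 170 ± 33.5 to 1853 ± 39.3 CPM (3.45 ± 0.11, edgeR adjusted p = 4.8e-12), Slc2a1 from 25.6 ± 8.36 to 373 ± 18.5 CPM, and Tpi1 by 3.28 ± 0.13 and Ldha by 1.98 ± 0.09 on the log2 scale. The neuronal enolase Eno2 fell (-2.07 ± 0.57). Of 41 other hypoxia-response genes 35 rose and none fell (37 adjusted over the list alone). The median was 1.87 (camera adjusted p = 3.8e-87 and adjusted p = 1.3e-07 with an estimated correlation). Examples were Bnip3 (4.31 ± 0.19), Nrn1 (4.12 ± 0.20), Fam162a (2.34 ± 0.11) and the oxygen sensor Egln1 (2.18 ± 0.10). Of 21 genes reported as HIF-2α-dependent 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Vegfa, Cited2 (1.23 ± 0.16), Angpt2 (2.47 ± 0.49) and Arg1 (3.01 ± 0.88) higher and Csf1r (-0.51 ± 0.09) lower (median 0.06, camera adjusted p = 0.23).

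Many interferon and cell division genes and some antigen presentation genes were lower in the Vhl/Hif2a knockout. Of 29 type I interferon response genes 20 fell and none rose (22 adjusted over the list alone), among them Irf7 (-1.56 ± 0.23), a transcription factor that amplifies the response, Ifit1 (-2.09 ± 0.31) and Ifit3 (-2.64 ± 0.43). The median was -0.70 (camera adjusted p = 1.6e-12 and adjusted p = 0.13 with an estimated correlation). The count was 13 without knockout 1. Of 14 MHC class II and antigen presentation genes 7 fell (9 adjusted over the list alone), among them Ciita (-0.98 ± 0.29) and the costimulatory genes Cd86 (-0.82 ± 0.18) and Cd40 (-1.88 ± 0.61). The median was -0.63 (camera adjusted p = 3.1e-04 and adjusted p = 0.37 with an estimated correlation). That count was 3 without knockout 1, 2 or 3 and 2 without control 2. Of 11 dendritic cell markers 6 fell (8 adjusted over the list alone), among them Ccr7 (-2.40 ± 0.33), Flt3 (-1.66 ± 0.28) and Fscn1 (-2.40 ± 0.47). The median was -1.17 (camera adjusted p = 7.9e-05 and adjusted p = 0.29 with an estimated correlation). The count was 3 without control 1 or control 2. Of 32 proliferation genes 26 fell (30 adjusted over the list alone), among them the division marker Mki67 (140 ± 23.6 against 249 ± 22.7 CPM) and Plk1 (-0.76 ± 0.10). The median was -0.51 (camera adjusted p = 1.1e-15 and adjusted p = 0.0039 with an estimated correlation).

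Cytokine, lipid and macrophage genes went both ways in the Vhl/Hif2a knockout. Of 22 inflammatory cytokines and chemokines 2 rose, Ccl9 (1.0 ± 0.18) and Nfkbia (0.64 ± 0.19), and 6 fell, among them Cxcl10 (-2.78 ± 0.36) and Il12b (-2.80 ± 0.46), with 3 and 6 adjusted over the list alone (median -0.34, camera adjusted p = 0.11). Of 30 lipid and surfactant handling genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Fabp4 (1.43 ± 0.15), Apoe (1.72 ± 0.22) and the scavenger receptor Msr1 (1.04 ± 0.19) higher. The median was 0.17 (camera adjusted p = 0.0096 and adjusted p = 0.37 with an estimated correlation). Of 34 alveolar macrophage identity genes 7 rose and 3 fell (7 and 3 adjusted over the list alone), with Itgax (0.45 ± 0.06) and Chil3 (0.43 ± 0.12) higher and Siglecf (-0.30 ± 0.09) lower. The median was -0.01, the mean 0.07 and the camera direction up (adjusted p = 0.55). Of 20 monocyte and interstitial macrophage genes 5 rose and 4 fell (6 and 4 adjusted over the list alone), with the integrin gene Itgam (2.80 ± 0.21) and Ccr2 (0.84 ± 0.22) higher and Tmem176a (-1.97 ± 0.44) and C1qb (-1.71 ± 0.48) lower. The median was -0.19, the mean -0.08 and the camera direction up (adjusted p = 0.55). Of 24 cholesterol synthesis and uptake genes 8 fell (13 adjusted over the list alone), among them Dhcr7 (-0.51 ± 0.10) and Fdft1 (-0.48 ± 0.11). The median was -0.29 (camera adjusted p = 5.2e-05 and adjusted p = 0.37 with an estimated correlation). The count was 4 without knockout 1, knockout 3 or control 2 and 5 without control 1. Of 49 cytosolic ribosomal protein genes 17 rose (44 adjusted over the list alone), among them Rps27 (0.60 ± 0.14). The median was 0.36 (camera adjusted p = 4.6e-09 and adjusted p = 0.60 with an estimated correlation). The count was 6 without knockout 1 or 2, 8 without knockout 3, 5 without control 1 and 8 without control 2. Of 7 neutrophil markers S100a8 rose (1.63 ± 0.19) and Cxcr2 (-1.79 ± 0.16) and Csf3r (-1.07 ± 0.11) fell (1 and 2 adjusted over the list alone, median -0.51, camera adjusted p = 0.18).

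With neither isoform left, in the triple knockout, 4 genes rose and 1, Vhl, fell. Plcb4, a phospholipase C, rose from 0.245 ± 0.0713 to 28.7 ± 3.40 CPM (6.83 ± 0.37, edgeR adjusted p = 2.0e-08). It was higher in the other knockouts as well, at 21.1 ± 0.623 against 0.897 ± 0.694 CPM in the Vhl/Hif1a cross and 14.7 ± 1.87 against 0.701 ± 0.290 CPM in the Vhl/Hif2a cross. Itgax, which encodes CD11c, rose from 1364 ± 9.80 to 2149 ± 58.0 CPM (0.66 ± 0.06, edgeR adjusted p = 6.8e-05, but adjusted p = 0.12 with only the triple libraries fitted) and Itgam, the adjacent integrin gene, from 5.87 ± 0.516 to 14.0 ± 0.907 CPM (1.25 ± 0.21, edgeR adjusted p = 0.035). Pagr1a rose from 2.71 ± 0.364 to 14.6 ± 5.66 CPM (2.43 ± 0.40, edgeR adjusted p = 0.035). The glycolytic and hypoxia genes raised in the other knockouts did not pass, with Pgk1 at 148 ± 5.66 against 149 ± 3.23 CPM and Egln3 at 0.265 ± 0.143 against 0.430 ± 0.271 CPM. Of 12900 genes 5 differed, while 1484 had an unadjusted p under 0.05 and DESeq2 called 13. With 1 library left out the count was 3 without knockout 1, knockout 3, or control 1, 2 or 3, and the calls of Pagr1a and Itgam ended without any 1 of the 6 libraries. Pagr1a then ranged from 2.07 (adjusted p = 0.30, without knockout 1) to 2.61 (0.051, without knockout 3), with adjusted p = 0.074 without knockout 2 and 0.17, 0.20 and 0.12 without control 1, 2 and 3. Itgam then had adjusted p = 0.29, 0.093 and 0.16 without knockout 1, 2 and 3 and 0.15, 0.20 and 0.11 without control 1, 2 and 3.

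Among the gene groups in the triple knockout, 1 member passed in alveolar macrophage identity (Itgax) and 1 in monocyte genes (Itgam), each 1 adjusted over the list alone, and no member of the other lists passed. Of 23 glycolysis genes 1 was higher and 3 lower adjusted over the list alone. The median was -0.20 (camera adjusted p = 4.4e-04 and adjusted p = 0.71 with an estimated correlation). Other hypoxia-response genes had a median of -0.00 (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.49), interferon genes of -0.19 (camera adjusted p = 0.11), inflammatory genes of -0.17 (0.96), proliferation genes of 0.03 (0.25), and genes reported as HIF-2α-dependent of -0.07 (0.45). Alveolar macrophage identity genes had a median of 0.16 (camera adjusted p = 4.4e-04 and adjusted p = 0.38 with an estimated correlation). MHC class II genes had a median of -0.29 (0.041, and adjusted p = 0.71 with an estimated correlation) and cholesterol genes of -0.15 (0.0047, and adjusted p = 0.71 with an estimated correlation). Monocyte genes (median -0.21, 0.58), lipid and surfactant genes (1 higher and 1 lower adjusted over the list alone, -0.00 with a mean of 0.02 and direction up, 0.49), ribosomal protein genes (-0.09, 0.19), neutrophil markers (0.23, 0.089) and dendritic cell markers (0.10, 0.77) were not called. Triple control 2 had 0.7245% mitochondrial counts, against 1.79% to 3.14% in the other 17 libraries.

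**Figure D2:**
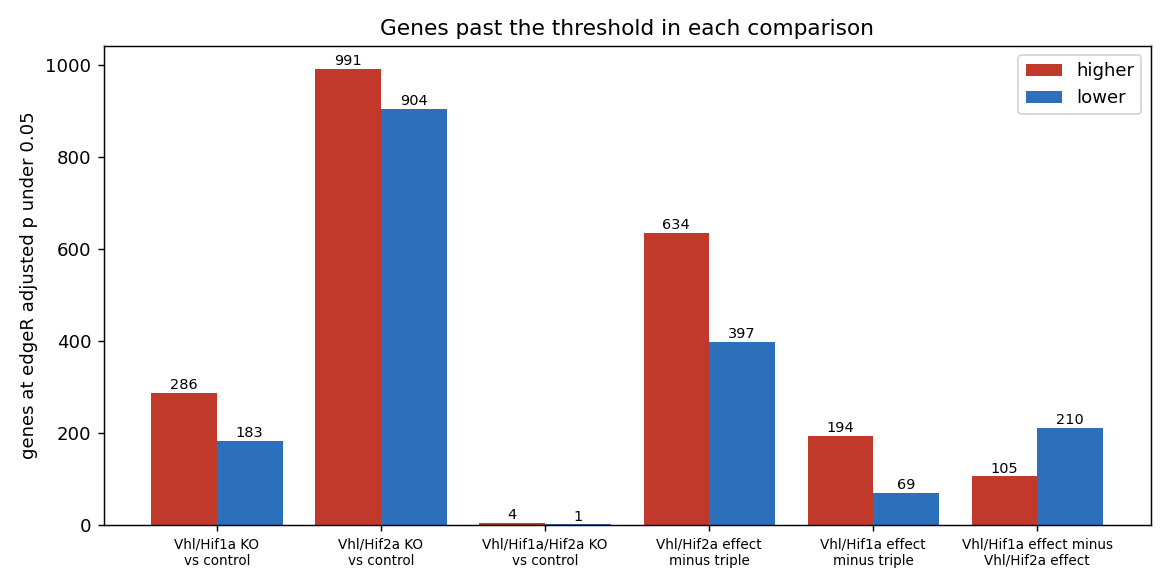
Number of genes at an edgeR adjusted p under 0.05 (bars from 0), higher and lower, in each knockout against its control and in each difference of effects. The Vhl/Hif2a knockout has 991 higher and 904 lower genes and the triple knockout 4 and 1.

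**Figure D3:**
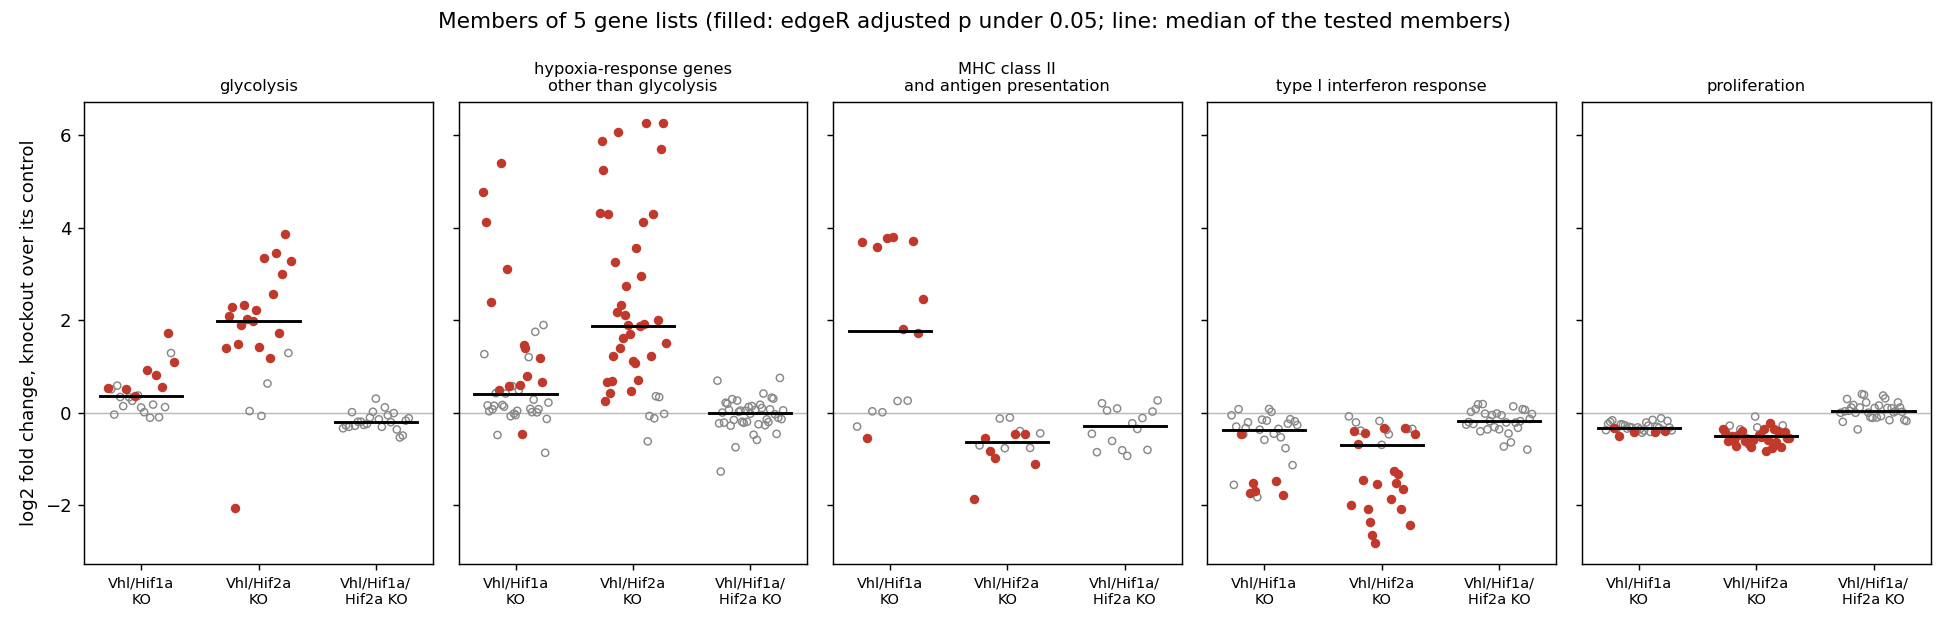
Log2 fold change of each tested member of 5 gene lists in the 3 knockouts, with filled points at an adjusted p under 0.05 and a line at the median. Glycolysis has medians of 0.35, 1.98 and -0.20 in the Vhl/Hif1a, Vhl/Hif2a and triple knockouts, and MHC class II 1.76, -0.63 and -0.29.

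Between the effects of the Vhl/Hif1a and Vhl/Hif2a knockouts, the gene lists with the largest median differences were MHC class II and glycolysis. Glycolysis genes were less raised in the Vhl/Hif1a knockout, with 18 of 23 lower and none higher (1 higher and 18 lower adjusted over the list alone). The median difference was -1.63 (camera adjusted p = 2.6e-133 and adjusted p = 8.4e-06 with an estimated correlation), and Pgk1 stood at -3.55 ± 0.15 (edgeR adjusted p = 3.0e-10). Of 41 other hypoxia-response genes 21 were lower (1 higher and 26 lower adjusted over the list alone). The median was -1.13 (camera adjusted p = 1.1e-56 and adjusted p = 8.8e-07 with an estimated correlation). MHC class II genes were higher in the Vhl/Hif1a knockout, with 8 of 14 past the test (11 adjusted over the list alone). The median difference was 2.51 (camera adjusted p = 6.7e-47 and adjusted p = 1.2e-04 with an estimated correlation). Ciita (4.56 ± 0.41, edgeR adjusted p = 3.4e-06), H2-Aa (4.54 ± 0.51), H2-Eb1 (4.48 ± 0.42), Cd74 (4.41 ± 0.48), H2-Ab1 (3.91 ± 0.49), H2-Ob (2.91 ± 0.52) and H2-Oa (2.82 ± 0.39) were among the 10 largest. Unc5a (3.26 ± 0.39), C3ar1 (3.19 ± 0.52) and Pdpn (2.89 ± 0.34) complete these, and Rgs11 (-5.42 ± 0.54), Tnfsf9 (-4.92 ± 0.87), Vmn2r26 (-4.04 ± 0.70), Ddit4 (-3.75 ± 0.68), Ddah1 (-3.68 ± 0.62) and Adra2a (-3.45 ± 0.47) were among the lowest. Vegfa (-7.15 ± 1.39, edgeR adjusted p = 0.0075) lost its call without Vhl/Hif1a control 2 (-6.42, adjusted p = 0.14) and was -8.26 without Vhl/Hif1a knockout 3 and -8.14 without Vhl/Hif2a control 1. Iqcg (-4.21 ± 0.98) lost its call without 7 single libraries (highest adjusted p = 0.30, at -3.29 without Vhl/Hif1a control 1) and was -4.87 without Vhl/Hif2a control 2. Without Vhl/Hif1a control 3, C3ar1 was 3.95 and Ddit4 -3.09. Ppp1r3g had 2 counts over the Vhl/Hif1a knockout libraries and 664 over the Vhl/Hif2a knockout libraries, and the call of its difference ended without any 1 of 7 libraries (adjusted p = 0.056 to 0.64, the highest without Vhl/Hif1a control 3). In all 315 genes differed, with 105 higher and 210 lower in the Vhl/Hif1a knockout.

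The effects of these knockouts also had much in common. Of the genes called higher, 202 were shared, against 21.971 if the calls were independent (one-sided Fisher exact p = 3.7e-163), and of those called lower 128 were shared, against 12.824 (one-sided Fisher exact p = 2.0e-106). These p-values treat genes as independent, which they are not, and do not measure the spread between libraries. Of 339 genes called in both, 9 went in opposite directions, and the test of the difference passed for each of the 9. Ciita (3.59 and -0.98), H2-Oa (1.71 and -1.11), H2-M3 (0.59 and -0.29) and Scml4 (0.92 and -0.65) were higher in the Vhl/Hif1a and lower in the Vhl/Hif2a knockout. Narf (-0.47 and 1.87), Cyp4f37 (-1.25 and 1.21), Plcb1 (-0.78 and 0.65), Tgm2 (-0.40 and 0.30) and Spn (-0.23 and 0.29) went the other way. Across the 12900 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.367 and a Spearman correlation of 0.442. With the triple knockout these were -0.122 and -0.213 for the Vhl/Hif1a knockout, with a Pearson value of 0.0211 without triple control 2, and -0.0270 and -0.113 for the Vhl/Hif2a knockout.

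**Figure D4:**
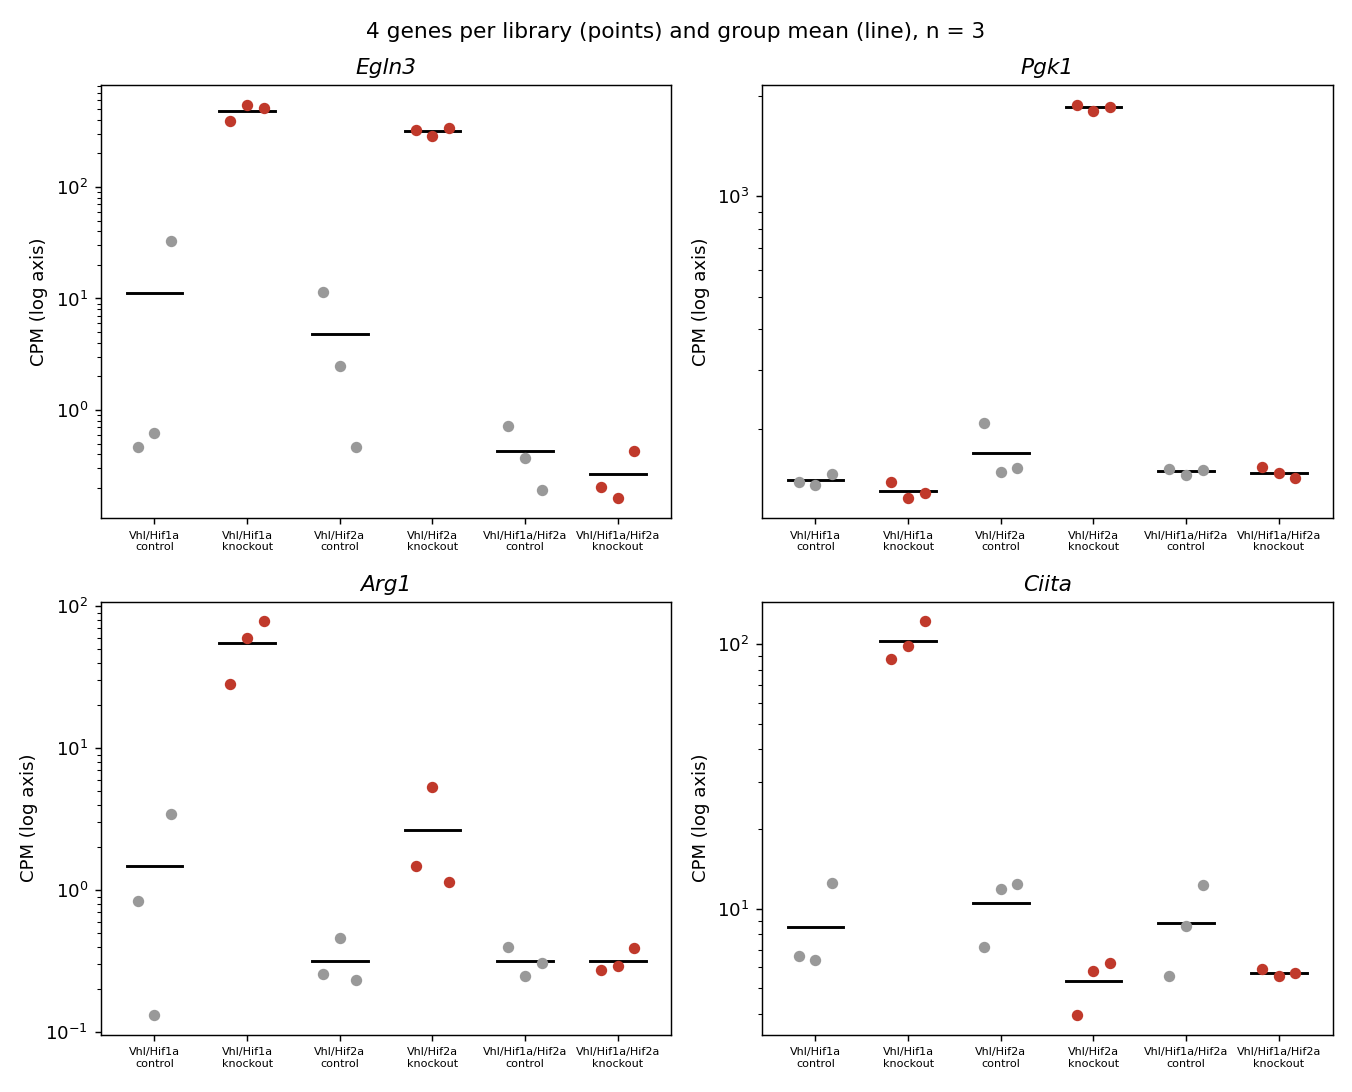
Egln3, Pgk1, Arg1 and Ciita in CPM (log axis) in each library of the 6 groups, with points for libraries and a line for the mean. Pgk1 is at 1853 CPM on average in the Vhl/Hif2a knockout and at 130 and 148 CPM in the Vhl/Hif1a and triple knockouts.

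Against the triple knockout, the effect of the Vhl/Hif2a knockout, where HIF-1α is left, was higher for glycolysis in 18 of 23 genes (18 and 1 lower adjusted over the list alone). The median was 2.09 (camera adjusted p = 6.5e-122 and adjusted p = 1.3e-05 with an estimated correlation). It was higher in 27 of 41 other hypoxia-response genes (34 adjusted over the list alone). The median was 1.86 (camera adjusted p = 5.5e-59 and adjusted p = 1.0e-06 with an estimated correlation). Proliferation genes were lower, with 16 of 32 past the test (25 adjusted over the list alone) and a median of -0.49 (camera adjusted p = 5.9e-14 and adjusted p = 0.0062 with an estimated correlation). Interferon genes were lower in 8 of 29 (15 adjusted over the list alone; camera adjusted p = 1.2e-07 and adjusted p = 0.33 with an estimated correlation). The highest genes included Hspa12b (6.57 ± 0.88), Ankrd37 (6.53 ± 0.83, edgeR adjusted p = 7.0e-05), Ppp1r3g (6.52 ± 1.13), Apbb1 (6.49 ± 0.99), Tnfsf9 (6.16 ± 1.11), Vmn2r26 (5.98 ± 0.84), the proteoglycan gene Sdc4 (5.32 ± 0.85) and Rgs11 (4.95 ± 0.61). Hif3a had 2 counts over the triple knockout libraries and 1213 over those of the Vhl/Hif2a knockout, and the call of its difference ended without any 1 of 7 libraries (adjusted p = 0.059 to 0.93, the highest without triple control 3). Ak4 (6.12 ± 1.44) lost its call without triple control 2 (adjusted p = 0.079) or 3 (0.055). The lowest were Fam167a (-3.57 ± 0.39, edgeR adjusted p = 1.5e-05), Dclk3 (-3.30 ± 0.62), Enpp5 (-3.13 ± 0.76, adjusted p = 0.056 without triple knockout 1), Spsb1 (-3.00 ± 0.35), the interleukin 12 subunit Il12b (-2.90 ± 0.63), Marchf4 (-2.87 ± 0.36), Unc5a (-2.76 ± 0.39), Scamp5 (-2.73 ± 0.38), Nat8l (-2.73 ± 0.40) and Epor (-2.72 ± 0.55). Single libraries moved some of these differences by over 1.5-fold. Without triple control 2, Hspa12b was 5.80, Ankrd37 5.85, Tnfsf9 5.23 and Epor -3.46. Without triple control 1, Vmn2r26 was 4.98 and Apbb1 5.84, without triple control 3 Ppp1r3g was 5.87, and without triple knockout 3 Tnfsf9 was 7.40. Without Vhl/Hif2a control 1, Ppp1r3g was 7.58, Apbb1 7.30 and Ak4 7.38, and without Vhl/Hif2a knockout 3 Enpp5 was -4.51, Dclk3 -3.97 and Il12b -3.49. In all 1031 genes differed (634 higher and 397 lower), with 687 without triple knockout 1, and 931 were called in the knockout and in this difference with the same sign, 49.1% of the 1895.

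Against the triple knockout, the effect of the Vhl/Hif1a knockout, where HIF-2α is left, was higher for MHC class II in 8 of 14 genes (9 and 1 lower adjusted over the list alone). The median was 1.93 (camera adjusted p = 1.1e-23 and adjusted p = 0.0043 with an estimated correlation). H2-Ab1 (4.74 ± 0.50), H2-Aa (4.59 ± 0.51), Cd74 (4.56 ± 0.48), H2-Eb1 (4.52 ± 0.42, edgeR adjusted p = 1.3e-05) and Ciita (4.2 ± 0.41) were among the 10 highest, with Ankrd37 (5.40 ± 0.81), Btnl4 (4.61 ± 0.50), C3ar1 (4.33 ± 0.54), Rtl5 (4.32 ± 0.38) and Abcb4 (4.65 ± 0.97, but 3.73 with adjusted p = 0.10 without triple control 3). Abcb4 was 5.59 and C3ar1 5.08 without Vhl/Hif1a control 3, Abcb4 was 5.41 without triple knockout 1, and Ankrd37 was 4.72 without triple control 2. Glycolysis was higher in 7 of 23 genes (16 adjusted over the list alone; median 0.60, camera adjusted p = 9.8e-15 and adjusted p = 0.053 with an estimated correlation). Other hypoxia-response genes were higher in 9 of 41 (15 adjusted over the list alone; median 0.48, camera adjusted p = 6.9e-10 and adjusted p = 0.0043 with an estimated correlation). None of 32 proliferation genes passed (17 lower adjusted over the list alone). The median was -0.37 (camera adjusted p = 4.2e-10 and adjusted p = 0.020 with an estimated correlation). The lowest were Pagr1a (-3.37 ± 0.56), Fam167a (-2.43 ± 0.38, edgeR adjusted p = 0.0015), Spag11b (-2.10 ± 0.40), Spsb1 (-2.09 ± 0.34) and the chemokine receptor gene Cxcr2 (-1.78 ± 0.22). Plcb4, Cxcl10, Awat1, Ifit1 and Clec1a were also called lower, but each call ended when any of several single libraries was left out. Plcb4 went from -2.31 to -1.43 without Vhl/Hif1a control 3 (adjusted p = 0.13), and the highest adjusted p was 0.11 for Cxcl10 without Vhl/Hif1a knockout 2, 0.15 for Awat1 without knockout 3, 0.13 for Ifit1 without control 3 and 0.093 for Clec1a without knockout 3. In all 263 genes differed (194 higher and 69 lower), and 234 were called in the knockout and in this difference with the same sign, 49.9% of the 469. Without Vhl/Hif1a knockout 2, knockout 3 or control 2 the 263 was 168, 161 or 162, without triple knockout 1, 2 or 3 it was 165, 174 or 172, and without triple control 3 it was 413. The 234 was 152, 144 and 141 without the first 3 of these and 155 without triple knockout 1.

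The 3 control groups differed from each other in 561 genes, so the crosses were not alike before any knockout. Xist, expressed from the inactive X chromosome, was at 386 ± 72.1 CPM in the Vhl/Hif1a and 548 ± 192 CPM in the Vhl/Hif2a controls and at 0.308 ± 0.0698 CPM in the triple controls. The Y-linked gene Ddx3y was at 0.0422, 0.0257 and 84.4 ± 32.5 CPM in the same order, and the knockout groups had the same pattern, with Xist at 426, 443 and 0.317 CPM. This is the pattern of female animals in the Vhl/Hif1a and Vhl/Hif2a crosses and male animals in the triple cross, though the labels give no sex. Sex by these genes is therefore confounded with the cross in all differences of effects that involve the triple cross. The count of 561 genes was 281 without Vhl/Hif1a control 2 and 331 without Vhl/Hif1a control 3.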

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

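The counts of other splits of the libraries were set before the data were examined, and all tests of explanations in this part were chosen after the results were seen. The effects of the knockouts differed between crosses by the tests of the differences, with 1031 genes between the Vhl/Hif2a and triple knockouts, 263 between the Vhl/Hif1a and triple knockouts and 315 between the Vhl/Hif1a and Vhl/Hif2a knockouts. In 9 genes the Vhl/Hif1a and Vhl/Hif2a knockouts were called in opposite directions. For Hif1a the effect of the Vhl/Hif2a knockout was below that of the triple knockout by a log2 difference of -1.90 (edgeR adjusted p = 1.1e-04). The effect of the Vhl/Hif1a knockout on Hif1a was above that of the Vhl/Hif2a knockout by 1.47 (edgeR adjusted p = 0.0027). For Epas1 the effect of the Vhl/Hif2a knockout was above that of the triple knockout by 1.21 (adjusted p = 0.0090). Groups of 3 libraries were not tested for single libraries far from the rest.

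In each knockout against its control, the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 469 genes in the Vhl/Hif1a cross (highest other 1), 1895 in the Vhl/Hif2a cross (highest other 13) and 5 in the triple cross (highest other 1), so that 1 of 10 splits reached the real count in each. Knockout and control labels were also drawn anew within each cross, 40 draws with the real one included. For the differences from the triple knockout 1 of 40 draws reached 1031 (highest other 500) and 1 of 40 reached 263 (highest other 21). For the genes called both in the knockout and in that difference 1 of 40 reached 931 (highest other 485) and 1 of 40 reached 234 (highest other 21). At that share this excludes chance labels without any knockout effect, but the draws cannot show whether 2 real effects differ. The draws with 416 to 500 genes for Vhl/Hif2a minus triple kept or turned round all labels of the Vhl/Hif2a cross. For the 315 genes between the Vhl/Hif1a and Vhl/Hif2a knockouts 4 of 40 draws, the real one included, gave as many, so the draws did not exclude chance. The other 3 gave 586, 737 and 871 genes, which points to a structure of the samples: they kept or turned round all labels of the Vhl/Hif2a cross and so held its whole effect, which leaves them little to say about chance. The 35 draws that mixed the labels of that cross gave at most 15 genes. Correlations were compared by size, whatever their sign. For the correlation between these knockouts 1 of 40 draws reached 0.367 (highest other 0.340). The margin was narrow, and with a single library left out the correlation could fall under 0.340, so chance was not clearly excluded. Correlations with the triple knockout were reached in size in 35 of 40 draws for the Vhl/Hif1a knockout (-0.122, highest other size 0.316) and in 26 of 40 for the Vhl/Hif2a knockout (-0.0270, highest other size 0.170), so chance was not excluded. Of 30 draws of the 9 control libraries into 3 groups, 1 reached 561 genes (highest other 14), which excludes chance at that share.

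Hif1a counts were called lower in the libraries labelled Vhl/Hif2a knockout, at 30.5% of control. In those labelled Vhl/Hif1a knockout they were at 84.5% of control, each below every control library, but did not pass (edgeR adjusted p = 0.66). Knockout labels exchanged between the crosses are argued against by the genes that separate the control groups, on which 6 of 6 knockout libraries lay nearer the controls of their own cross (positions -0.0616 to 0.0792 and 1.02 to 1.05, with the Vhl/Hif1a controls at 0 and the Vhl/Hif2a controls at 1). Exchanged labels of both whole crosses are argued against as well, since 0 of 9 genes near Hif1a or Epas1 that differ between the controls had the pattern this would give and 8 had that of the labels, such as Prkce near Epas1 (4.32 and 4.10 above the Vhl/Hif1a controls) and Arg2 near Hif1a (3.74 in the Vhl/Hif2a against the Vhl/Hif1a controls). These genes share the regions around Hif1a on chromosome 12 and Epas1 on chromosome 17, so they are not separate pieces of evidence. A lower level of Hif1a RNA where Vhl is lost and HIF-1α is kept stays open as a hypothesis. Both differences for Hif1a passed (larger edgeR adjusted p = 0.0027), but they restate the fall that prompted the hypothesis and so do not test it. The design also confounds the hypothesis with the cross, and counts per gene do not show exons.

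Genes called higher in the triple knockout were Plcb4, Itgax, Itgam and Pagr1a. HIF-1α activity left in these cells at the level of the Vhl/Hif2a knockout is argued against by 53 glycolysis and other hypoxia-response genes. These were called higher in the Vhl/Hif2a knockout, where their median was 2.10. In the triple knockout their median log2 fold change was -0.11 (quartiles -0.27 and 0.05). The genes were chosen where HIF-1α is left, and both lists rose less in the Vhl/Hif1a knockout. The test therefore cannot decide on HIF-2α activity. A transgene carried by knockout animals alone may raise genes near Itgax, whose promoter drives the recombinase. The 7 genes within 100 kb of Itgax other than Itgax and Itgam had medians of 0.37, 1.61 and 0.56 in the Vhl/Hif1a, Vhl/Hif2a and triple knockouts (1, 4 and 0 called higher). The 51 genes up to 1 Mb away had medians of 0.06, 0.04 and -0.11 (0, 4 and 0 called higher). Itgax itself passed in the Vhl/Hif2a (0.45 ± 0.06) and triple (0.66 ± 0.06) knockouts. It did not pass in the Vhl/Hif1a knockout (0.15 ± 0.06, edgeR adjusted p = 0.31), while Itgam passed in each. Plcb4 lies on chromosome 2, so the genes near Itgax do not bear on its rise. Cre and the loss of Vhl came together and cannot be told apart. The labels name Cre for knockouts alone without saying that controls lack it. Reads shared with the overlapping gene Pagr1b are argued against as the whole source of the rise of Pagr1a, since the sum of both genes was still higher (1.77 ± 0.37, against 2.43 ± 0.40 for Pagr1a alone). The call ended for the sum (adjusted p = 0.33, against 0.035), with a smaller fold and a like error, as Pagr1b had 14, 20 and 0 counts in the knockout and 35, 50 and 48 in the control libraries.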

How the results depend on the processing

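The alternatives that left out libraries for standing apart or set a minimum log2 fold change of 1 were chosen after the results were seen. Median-of-ratios scaling gave 467, 1893 and 5 genes in the Vhl/Hif1a, Vhl/Hif2a and triple knockouts, against 469, 1895 and 5. It moved the median of all genes by at most 0.0097 on the log2 scale. Dropping the filter gave 451, 1621 and 6 genes, and the stricter filter 482, 1853 and 5. Of 2024 values for named genes under alternatives, 1881 kept their side of the threshold, 142 lost it, 1 gained it and 0 reversed.

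The limma-voom test with quality weights called more: 1337, 3302 and 13 genes in the Vhl/Hif1a, Vhl/Hif2a and triple knockouts, 2056 for Vhl/Hif2a minus triple, 726 for Vhl/Hif1a minus triple, 804 for Vhl/Hif1a minus Vhl/Hif2a, 1707 among the controls, and 1903 and 638 called both in the Vhl/Hif2a or Vhl/Hif1a knockout and in its difference from the triple knockout. DESeq2 gave 13 in the triple knockout, 470 and 482 for the differences of Vhl/Hif1a from triple and from Vhl/Hif2a, 1296 among the controls and 354 called both in the Vhl/Hif1a knockout and against triple. With only the libraries compared the triple knockout had 2, Vhl/Hif2a minus triple 680 and the controls 106. Knockouts compared directly, without controls, gave 2485, 1701 and 1153, a comparison that holds the differences between crosses. No pairing of libraries was used in the main fit: 3 of 9 knockout libraries correlated best with the control of their own number, and 1 of 9 pairs exceeded 0.1. With 3 libraries per group this check cannot show that no pairs existed. The replicate block gave 313, 1440 and 4 in the knockouts, and 150 for Vhl/Hif1a minus triple, 194 for Vhl/Hif1a minus Vhl/Hif2a and 137 for the Vhl/Hif1a genes called in both. Without the 3 libraries that stand apart (Vhl/Hif1a control 3, Vhl/Hif2a control 1 and triple control 2) the Vhl/Hif1a knockout had 760, the triple knockout 3, and the correlation of Vhl/Hif1a with triple was 0.0305. A minimum absolute log2 fold change of 1 left 210, 686, 505, 158 and 197 genes for the Vhl/Hif1a and Vhl/Hif2a knockouts, Vhl/Hif2a minus triple, Vhl/Hif1a minus triple and Vhl/Hif1a minus Vhl/Hif2a. Genes at a mean CPM of at least 5 raised the correlation of the first 2 to 0.566. Why it rose was not tested.

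With each library left out in turn the Vhl/Hif1a knockout had 282 to 369 genes, the Vhl/Hif2a knockout 1227 to 1625, the triple knockout 3 to 4, Vhl/Hif2a minus triple 687 to 1406, Vhl/Hif1a minus triple 161 to 413, Vhl/Hif1a minus Vhl/Hif2a 216 to 280. The controls had 281 to 820, and the genes called in both 649 to 1101 (Vhl/Hif2a) and 141 to 256 (Vhl/Hif1a). The correlations ranged from 0.327 to 0.387, from -0.171 to 0.0211 and from -0.0466 to 0.00595. Of 54 list calls by camera, median-of-ratios scaling ended 0, an estimated correlation 37, fry 22, the replicate block 1 and leaving out the 3 libraries that stand apart 9. Lists newly called numbered 5 with fry, 4 with the replicate block and 11 without those 3 libraries. Numbers of called list members moved as well. In the Vhl/Hif1a knockout, proliferation (5 lower) had 0 with the replicate block, 2 without the filter, 22 with limma-voom, 8 with DESeq2 or with only the libraries compared, 11 without the 3 libraries that stand apart and 2 without the 2 knockout-like controls. Interferon (6 lower) had 3 with the block, 2 with only the libraries compared, 3 without the 3 libraries and 1 without the 2 controls, inflammatory genes (6 lower) 3 with the block, and glycolysis (8 higher) 14 with limma-voom. In the Vhl/Hif2a knockout, ribosomal protein genes (17 higher) had 5 with the block, 45 with limma-voom, 28 with DESeq2, 29 with only the libraries compared, 27 without the 3 libraries and 5 without the 2 controls. Dendritic cell markers (6 lower) had 3 with the block, with only the libraries compared and without the 3 or the 2 libraries. Without the 2 controls proliferation had 17 (of 26) and cholesterol genes 5 (of 8). The depth of 19.23 to 34.015 counts per CPM before TMM scaling limits genes near 1 CPM. With 200 genes changed, simulated 1.5-fold changes were found in 43.75%, 53.2% and 54.2% of genes in the 3 knockouts, and real recovery may be lower.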

Other observations

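The tests of explanations for transcripts in Vhl/Hif1a control 3 were chosen after the result was seen, and the gene lists before the data were examined. Of 76 oxidative phosphorylation genes none passed in the Vhl/Hif1a knockout (0 adjusted over the list alone, median 0.13, camera adjusted p = 0.018 and adjusted p = 0.80 with an estimated correlation). In the Vhl/Hif2a knockout 2 rose, with Ndufv3 at 1.0 ± 0.14, and 2 fell, with Ndufa4, the subunit that Ndufa4l2 resembles, at -1.41 ± 0.13 (2 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.32). In the triple knockout the median was -0.13 (adjusted p = 5.1e-04, and 0.71 with an estimated correlation). Of 25 tricarboxylic acid cycle genes 0, 2 and 0 fell in the Vhl/Hif1a, Vhl/Hif2a and triple knockouts (camera adjusted p = 0.36, 0.60 and 0.42). Of 30 fatty acid oxidation genes 1 rose in the Vhl/Hif1a knockout, 5 rose and 3 fell in the Vhl/Hif2a knockout and none passed in the triple knockout (camera adjusted p = 0.49, 0.60 and 0.62). Of 19 fatty acid synthesis and desaturation genes 1 rose and 3 fell in the Vhl/Hif1a knockout, with Acly, which makes acetyl-CoA, at 0.94 ± 0.09 and the desaturase Fads1 at -0.80 ± 0.19. In the Vhl/Hif2a knockout 2 rose and 3 fell, with Fads1 at -2.65 ± 0.21 and Scd1 at 0.67 ± 0.19. The median was 0.10, the mean -0.21 and the camera direction down, and in the triple knockout none passed (camera adjusted p = 0.92, 0.23 and 0.14 in the 3 knockouts).

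Stress and effector lists were mixed. Of 32 oxidative stress and iron genes 1 rose, the transferrin gene Trf (0.70 ± 0.08), and 3 fell in the Vhl/Hif1a knockout (median -0.17, camera adjusted p = 0.0041 and adjusted p = 0.53 with an estimated correlation). In the Vhl/Hif2a knockout 1 rose and 7 fell, with Txnrd1 at -0.78 ± 0.12 (median -0.22, 0.016 and adjusted p = 0.71 with an estimated correlation), and in the triple knockout none passed (0 higher and 2 lower adjusted over the list alone, median -0.20, 7.9e-05 and adjusted p = 0.71 with an estimated correlation). Of 17 alternative activation genes 1 rose and 1 fell, then 4 rose and 1 fell, then none passed (1 lower adjusted over the list alone) in the Vhl/Hif1a, Vhl/Hif2a and triple knockouts (camera adjusted p = 0.82, 0.55 and 0.42; in the first the median was -0.03 and the mean 0.28). Of 33 lysosome and phagocytosis genes 2 rose and 2 fell in the Vhl/Hif1a knockout and 2 rose and 4 fell in the Vhl/Hif2a knockout, with the inhibitory Fc receptor gene Fcgr2b at 1.58 ± 0.16 and 1.11 ± 0.16 and the activating Fcgr1 at -0.48 ± 0.11 and -0.68 ± 0.11. None passed in the triple knockout (camera adjusted p = 0.95, 0.30 and 0.42). Of 20 amino acid stress genes 1 fell in the Vhl/Hif1a knockout, 2 rose and 6 fell in the Vhl/Hif2a knockout, with the serine synthesis gene Phgdh at -0.82 ± 0.14 and Shmt2 at 1.03 ± 0.13 (median -0.12, mean 0.06). None passed in the triple knockout (camera adjusted p = 0.29, 0.60 and 0.062). Of 19 dissociation and immediate early genes 1 rose (Ier3, 2.09 ± 0.41), 2 rose (Ier3, 2.34 ± 0.40, and Dnajb1, 0.47 ± 0.15) and none passed (camera adjusted p = 0.93, 0.18 and 0.053). No sex-linked gene of 5 passed in any knockout (camera adjusted p = 0.92, 0.66 and 0.065).

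Markers of other cells were few after filtering. Of 12 lung epithelium genes Hopx rose (1.11 ± 0.23) and Epcam fell (-1.0 ± 0.17) in the Vhl/Hif1a knockout, Hopx (2.74 ± 0.24), Muc1 (0.91 ± 0.25) and Cdh1 (0.54 ± 0.11) rose in the Vhl/Hif2a knockout, and none passed in the triple knockout (camera adjusted p = 0.93, 0.23 and 0.47). Of 2 B cell markers Ighm fell in the Vhl/Hif2a knockout (-1.67 ± 0.52) and none passed in the triple knockout (1 higher adjusted over the list alone, camera adjusted p = 0.60 and 0.42). Of T and NK cell markers 1 was tested, Il7r (-0.82 ± 0.36, -0.60 ± 0.35 and -0.22 ± 0.36), with adjusted p = 0.31, 0.31 and 0.75, and of 10 eosinophil and mast cell markers 0 were tested. Neither 2 endothelium and fibroblast markers (camera adjusted p = 0.41, 0.78 and 0.42) nor 3 erythrocyte markers (0.65, 0.73 and 0.45) passed in any knockout. Clmn was at 214, 193 and 234 CPM in the Vhl/Hif2a knockout libraries and at 179, 224 and 188 CPM in their controls, against 0.0832 to 0.745 CPM in the other 12 libraries.

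Vhl/Hif1a control 3 held transcripts typical of the knockout, such as Egln3, and so did Vhl/Hif2a control 1 at a lower and less even share (median 2.71% over 39 genes, 61.5% of them within 2-fold), which leaves its source open. A candidate explanation for Vhl/Hif1a control 3 is material or reads of knockout cells of the same cross: of 24 genes specific to the knockout, chosen without this library, 87.5% lay within 2-fold of the median share, which was 6.61% of the knockout level. HIF activity in control cells that keep Vhl is argued against by 1 gene, Plcb4, which was also higher in the triple knockout. It stood at 0.881 of that median share. Plcb4 rose in all 3 knockouts, so loss of Vhl in part of the control cells could raise it too. The test cannot tell that case from mixed material. Reads of a library of the Vhl/Hif2a cross are argued against too, since Clmn stood at 0.307% of its level in the Vhl/Hif2a knockout. Clmn was low in the triple cross, so it does not test reads from there. No biological explanation other than HIF activity was tested, and whether cells, RNA or reads were mixed stays open, as does the level of Vhl in this library (13.15 CPM against 18.7 and 18.9 in the other controls), lower than that share alone would give.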
